A study of Homo sapiens with 2 samples.

How the data were processed

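RNA of 2 cultures of human epidermal keratinocytes, 1 from the sole of the foot (volar) and 1 from the top of the foot (nonvolar), was measured on 1 microarray each. Per the labels, both cultures came from 1 donor, were grown in KGM-GOLD, a keratinocyte growth medium, to passage 4, and received no treatment. The title and the passage label of the volar sample give passage 4, while its description speaks of early or late passage without saying which, so the passage was taken from the title and label. Total RNA was isolated with the RNeasy kit and labelled with biotin, per the labels' protocols, by a kit for 3' in vitro transcription (GeneChip HT 3' IVT Express). This kit primes at the poly(A) tail, so signal comes mostly from the 3' ends of transcripts.

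The deposited values are log2 values of 49395 probe sets per array, made by RMA, with Partek also named, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and combines the probes of each probe set. Software versions, and which arrays were normalized together, are not given in the sources used here. The log2 scale was inferred from the values, which ran from 2.23 to 14.4 on the volar array and from 2.29 to 14.4 on the nonvolar array. The normalization fixes the overall distribution of the arrays to be nearly equal, so a difference in total RNA per cell cannot be seen. RMA values carry no detection call. Near the bottom of the scale they are mostly background, which shrinks differences.

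Probe sets were named from the platform annotation, with symbols updated through the gene identifier for the 44967 probe sets whose identifier matched the reference table. Of all probe sets, 44994 named 1 gene, 1832 named several genes, 2473 named none here and 102 were the array maker's controls. Only probe sets naming 1 gene entered the gene table. For each gene the probe set with the highest mean of both arrays was used, which gave 18070 genes. Genes that could identify a donor were left out. A gene counted as measured when the higher of its 2 values was at or above the median of all probe set values pooled over both arrays, 5.62, which left 10588 genes. This filter is a convention and does not show that a transcript was absent below it. Where the lower value of a gene lay below 5.62, its fold difference is given as "at least", with that value raised to 5.62.

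The design has 1 array per site, so no test was run and no p-value, standard deviation or standard error is given. Differences are log2 volar minus nonvolar. Genes are described as at least 2-fold higher or lower. For 34 gene lists, the median difference of the measured members was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart when its median lay outside the central 95% of the random lists. Lists with fewer than 5 measured members were given no percentile. The 34 lists held 844 genes, of which 776 were analysed and 560 measured. The percentile describes these 2 arrays and says nothing about other cultures or donors. Genes of a list are not independent of each other, so a percentile is not a p-value. The lists, the filter, the thresholds and the rule for named genes were chosen before the data were examined.

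Named genes were the 12 measured genes with the largest difference in each direction whose other measured probe sets all had the same sign, up to 4 measured members of each list with the largest absolute difference, and 13 genes always named, of which 9 were analysed here. A gene with no other measured probe set also met the sign rule. Among the 12 lower genes only FN1 and LCE3D had another measured probe set, and among the 12 higher genes KRT2, DAPL1 and NCAPG had none. Genes named beyond this rule are marked as such. Precision was checked within the arrays only, through the other probe sets of each gene and through the spike-in control probe sets. The number of arrays, 1 per site, limits what the differences can show about the sites.

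Before use, the calculations were tested on simulated data for the volar against nonvolar comparison, with 200 of the 10588 measured genes shifted by known amounts and noise of the size seen between arrays. The 2-fold rule recovered 86% of 50 genes with a true log2 difference of 1.5, 94% of 50 genes at -1.5, and 100% of 50 genes at 3 and of 50 at -3. It was also passed by 0.789% of the unchanged genes. Of 200 unchanged lists, 3.5% fell outside the central 95%, and 100% of 50 lists shifted by 0.5 were placed as higher. The simulated noise was independent between genes and sized from the volar minus nonvolar differences themselves. These rates therefore do not cover genes that vary together or variation between cultures.

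The results were recomputed with no level filter, with a filter at the 75th percentile, with the median of a gene's probe sets, with only the probe sets that lack the suffixes for shared targets (_x_at and _s_at), with differences centred on their median, with quantile normalization, with a loess trend on level removed, with a pseudocount of 32 on the linear scale, and with a 1.5-fold threshold. An alternative with values below the filter raised to it was chosen after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.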

Results

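Gene expression was compared between cultured keratinocytes from volar skin, the thick hairless skin of the sole, and from nonvolar skin on the top of the foot. The question stated by the design is which genes mark the site of origin once the cells are in culture. Each site was represented by 1 primary isolate of the same donor and by 1 array, so every difference below lacks a replicate check. The medians of all probe sets were 5.61 on the volar and 5.62 on the nonvolar array, and 10200 and 10220 genes lay above the level filter of 5.62. Values are log2 RMA values.

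The volar culture had more RNA of the sole keratin KRT9 and of cell cycle genes, and less RNA of the genes of the cornified envelope, the protein shell of the outermost epidermal cells. KRT9, a type I keratin of palm and sole epidermis, read 12.83 in volar and 6.80 in nonvolar cells, a 65.2-fold difference, the largest in that direction under the naming rule. In the other direction KRT23, a type I keratin, read 4.11 in volar and 10.29 in nonvolar cells, at least 25.5-fold lower in volar. With low values raised to the filter it was not the largest, and SPRR3 (at least 48.3-fold) and FN1 (at least 39.5-fold) were among those above it. Of 10588 measured genes, 314 (2.97%) were at least 2-fold higher in volar and 449 (4.24%) at least 2-fold lower. At least 4-fold differences were seen for 78 genes higher and 148 lower. The other array was below the filter for 129 of the 314 and 173 of the 449, and with such values raised to the filter the counts were 245 and 366.

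**Figure D1:**
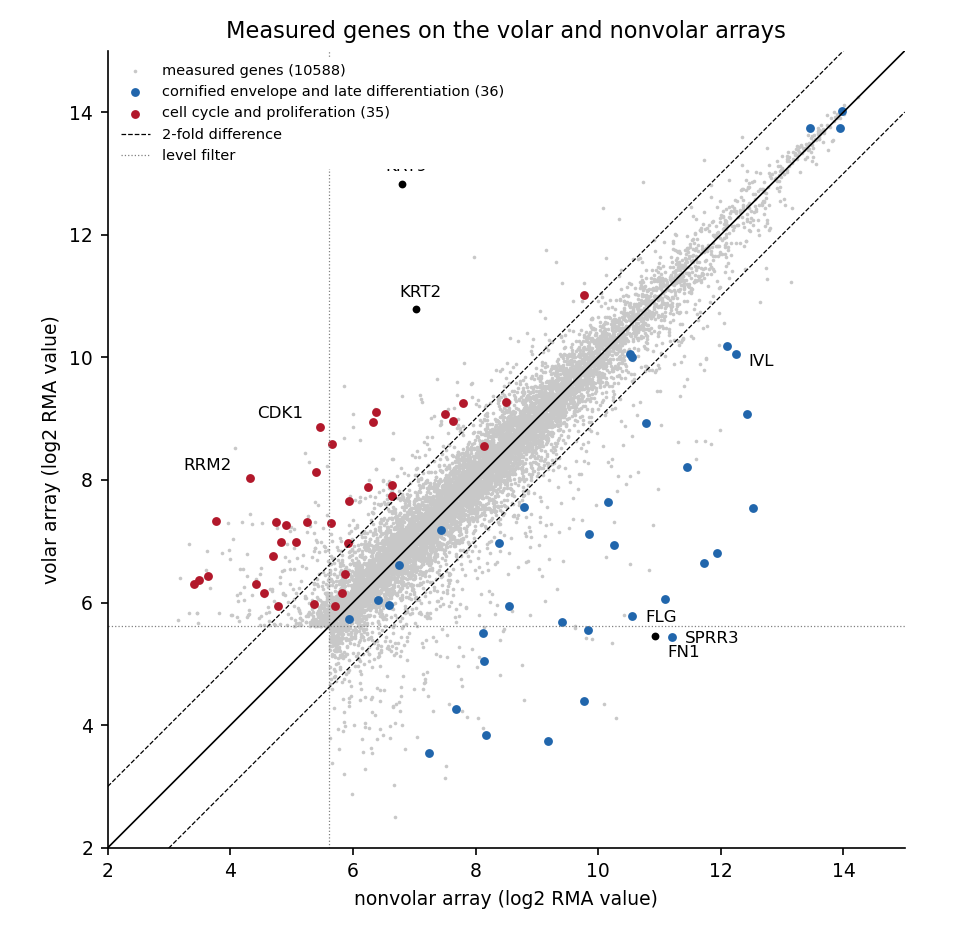
Each point is 1 of 10588 measured genes, with its log2 RMA value on the nonvolar array (x axis) and on the volar array (y axis); dashed lines mark 2-fold differences and dotted lines the level filter of 5.62. Of the 35 cell cycle genes (red), 29 lie above the upper dashed line, and of the 36 cornified envelope genes (blue), 26 lie below the lower one.

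The keratins of the spinous layers, where cells leave the basal layer and start to differentiate, were mostly at or above the nonvolar level. KRT2, a keratin of the upper epidermis, was 13.5-fold higher in volar cells (10.78 against 7.02). KRT1 was 2.40-fold higher (13.60 against 12.34), while its partner KRT10 differed by 1.58-fold (13.41 against 12.76). KRT77 went the other way and was at least 5.39-fold lower in volar cells. Among 17 measured genes of the early differentiation list, 2 were at least 2-fold higher and 1 lower, and the median difference of 0.18 lay inside the random range, at percentile 97.23. With the stricter level filter the list stood apart as higher, with a median of 0.22 at percentile 99.09. A pseudocount also placed it as higher, at percentile 97.865. The basal keratins KRT5 (14.11 against 14.01) and KRT14 (14.25 against 14.24) were near the top of the scale on both arrays, close to its maximum of 14.4. Of 6 listed palmoplantar keratins, only 2 entered the gene table, and both were measured. KRT6A, KRT6B, KRT16 and KRT17 were not analysed, so their levels in these cultures were not assessed. Besides KRT9 the measured member was KRT6C, which read 13.96 and 13.73 and whose probes may also read its near-identical paralogs.

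**Figure D2:**
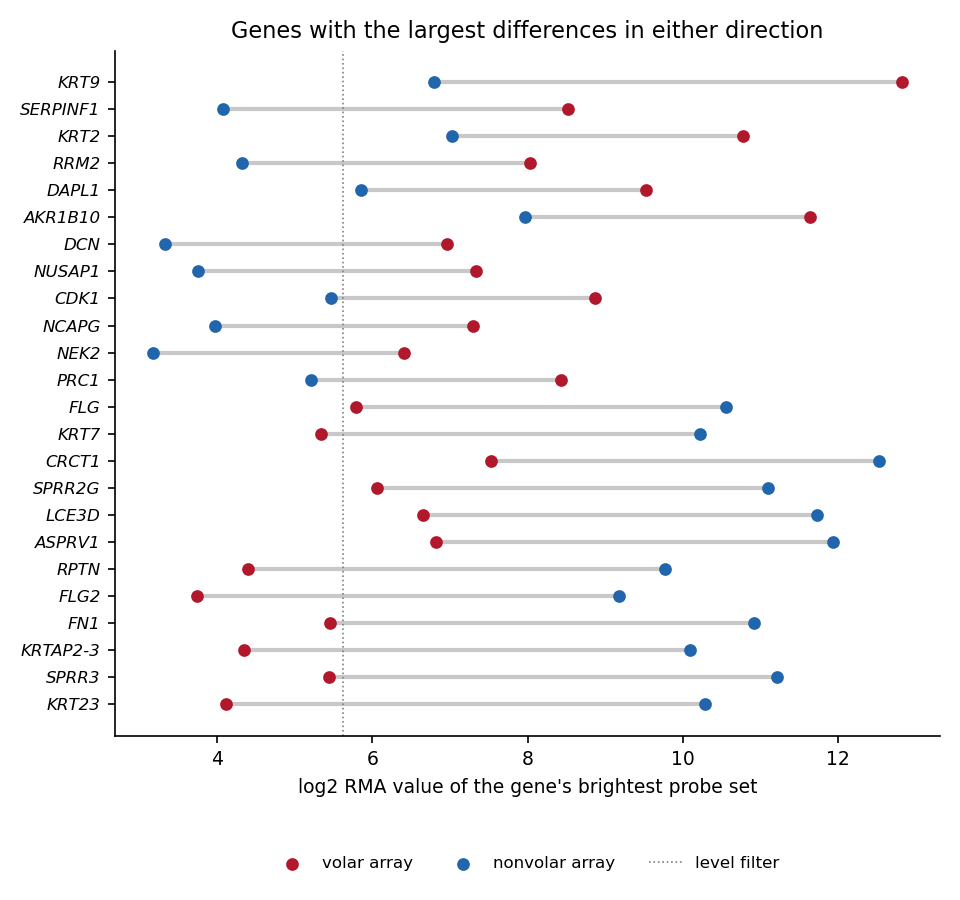
Log2 RMA value (x axis) on the volar array (red) and the nonvolar array (blue) of the 12 genes with the largest difference in each direction under the naming rule; the dotted line is the level filter of 5.62, and a dot left of it gives only a bound on the fold. KRT9 has the longest bar among genes higher in volar, from 6.80 to 12.83, and KRT23 among genes lower in volar, from 10.29 to 4.11.

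Late differentiation genes formed the group with the largest median difference among all lists given a percentile. Of 36 measured genes of the cornified envelope list, 26 were at least 2-fold lower in volar cells and 0 higher. Their median difference was -2.67, below all 10000 random lists, whose central 95% ran from -0.11 to 0.15. With values below the filter raised to it, the median was -2.51. Filaggrin (FLG), which bundles keratin filaments, was 27.3-fold lower (5.79 against 10.56), and the related FLG2 and repetin (RPTN) were at least 11.8-fold and 17.9-fold lower. ASPRV1, a protease that processes filaggrin, was 34.8-fold lower (6.82 against 11.94). CRCT1 was 31.8-fold lower, and the small proline-rich genes SPRR2G and SPRR3 were 32.7-fold and at least 48.3-fold lower. Involucrin (IVL), a scaffold of the envelope, was 4.53-fold lower (10.06 against 12.24). Other members, named here beyond the rule, differed by less than 2-fold, among them EVPL (-0.25), PPL (-0.47), TGM1 (-0.54) and SPRR1B (0.03). LCE3D was 33.7-fold lower by its brightest probe set, but its other measured probe set differed by -0.92 only, and SPRR and LCE genes have close paralogs that may share probes.

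Genes of desquamation and of barrier lipids were also lower in volar cells. Of 19 measured kallikreins and protease inhibitors, 10 were at least 2-fold lower and 0 higher, with a median of -1.03 at percentile 0. KLK7 and KLK5, proteases that release cells from the skin surface, were 8.70-fold and 4.54-fold lower, and CST6, a cysteine protease inhibitor, was 4.51-fold lower. SPINK7 read 2.89 in volar and 5.99 in nonvolar cells. In the barrier lipid list, 3 of 20 measured genes were at least 2-fold lower, among them the ceramidase ACER1 (at least 2.39-fold) and the glucosylceramide synthase UGCG (2.31-fold). That list had a median of -0.34 at percentile 0.06 and fell inside the random range with the stricter filter (-0.19, percentile 3.525). The 14 measured sterol synthesis genes had a median of -0.04, inside the random range, with none at 2-fold. Of these, 8 differences were negative and 6 positive, and the farthest from 0 were HSD17B7 (0.53), SC5D (-0.47), MVD (0.45) and MSMO1 (-0.26).

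Cell cycle genes were higher in volar cells. Of 35 measured genes, 29 were at least 2-fold higher, 0 were lower, and all 35 differences were positive. Their median of 1.71, a 3.27-fold difference, lay above all 10000 random lists, and was 1.32 with low values raised to the filter. RRM2, a subunit of the enzyme that makes deoxyribonucleotides, was at least 5.34-fold higher (8.03 against 4.32), and CDK1, the kinase that drives entry into mitosis, at least 9.52-fold higher (8.87 against 5.46). Topoisomerase TOP2A was 7.59-fold higher and the proliferation marker MKI67 at least 2.57-fold higher, or 0.99 on the log2 scale by the median of its probe sets. Among other mitotic genes, NUSAP1 was at least 3.29-fold, the condensin subunit NCAPG at least 3.19-fold and the cytokinesis gene PRC1 at least 7.04-fold higher. NEK2 read 6.41 against 3.17, which bounds its difference at only 1.73-fold. In the list of p53 targets and senescence genes the median was -0.37 at percentile 0.06, with 2 of 17 measured genes at least 2-fold lower. These were IGFBP7 (4.76-fold, though -0.38 by its other probe set) and CDKN2A. CDKN2A, the locus of the cell cycle inhibitor p16, was 2.25-fold lower by its brightest probe set, while its other 2 probe sets were higher in volar by 0.35 and 0.43, so its direction is open. CDKN2B was 1.51-fold higher and GDF15 1.97-fold lower.

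**Figure D3:**
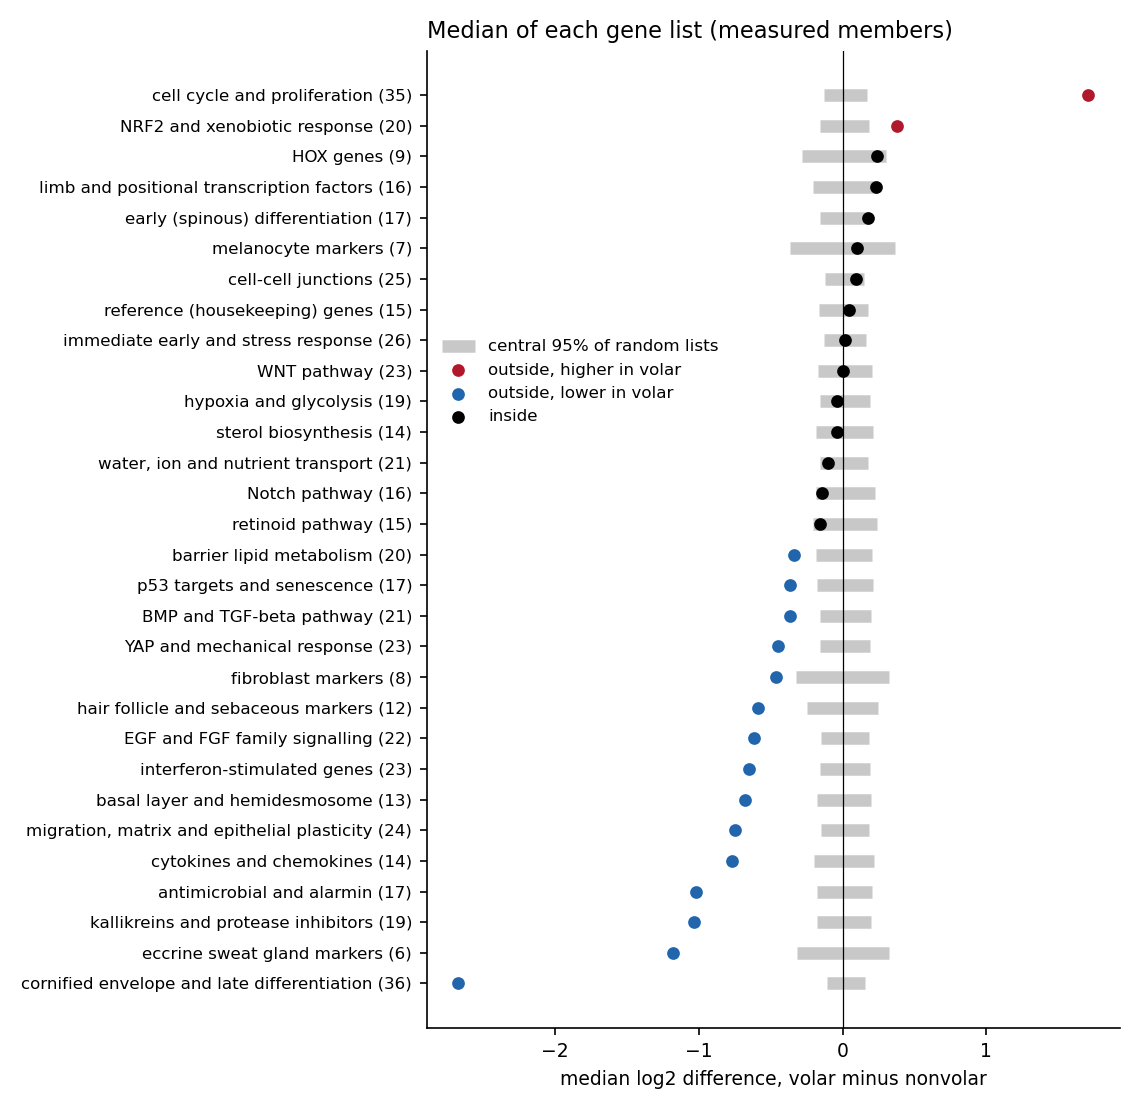
Median log2 difference, volar minus nonvolar (x axis), of the measured members of each of the 30 gene lists given a percentile, with the number of measured members in brackets; grey bars are the central 95% of 10000 random lists matched on level. The cell cycle list (1.71) and the NRF2 and xenobiotic list (0.38) lie to the right of their bars, 15 lists lie to the left, and the cornified envelope list (-2.67) is the farthest.

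Antimicrobial, inflammatory and interferon-stimulated genes were lower in volar cells. Of 17 measured antimicrobial and alarmin genes, 10 were at least 2-fold lower and 0 higher, with a median of -1.02. The iron-binding protein LCN2 was 12.4-fold lower (7.27 against 10.90), S100A7 at least 7.18-fold, the elastase inhibitor PI3 6.46-fold and RNASE7 6.28-fold lower. S100A8 (13.79 against 13.63) and S100A9 (13.20 against 13.48), named here beyond the rule, differed little and read high on the scale. The cytokine list had a median of -0.77, or -0.50 with no level filter, with 6 of 14 measured genes at least 2-fold lower. IL1B was 5.51-fold lower, CXCL8 at least 4.43-fold and CCL5 at least 3.84-fold, while IL33 read 3.20 against 5.86. Of 23 measured interferon-stimulated genes, 5 were at least 2-fold lower and 0 higher, with a median of -0.65. IFI27 was 5.73-fold, IFI6 3.58-fold, IFITM1 2.67-fold and MX1 2.52-fold lower. Each of these lists had a percentile of 0.

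Genes of anchorage, matrix and mechanical response were lower in volar cells as groups. In the basal layer and hemidesmosome list the median was -0.68, at percentile 0. There ITGA2 was 2.94-fold, the laminin chain LAMB3 2.37-fold and ITGB4 2.24-fold lower, 3 of 13 measured genes, whereas the anchoring collagen COL7A1 was 1.89-fold higher. In the list of migration and matrix genes, 10 of 24 measured members were at least 2-fold lower and 0 higher, with a median of -0.75 at percentile 0, or -0.35 with no level filter. Fibronectin (FN1) was at least 39.5-fold lower (5.45 against 10.92) by its brightest probe set, its other 6 measured probe sets were lower by log2 differences of -5.27 to -2.31, and the intermediate filament gene VIM was 9.51-fold lower (8.35 against 11.60). PLAUR was 3.98-fold lower, and LOXL2 read 3.91 against 5.83. Of 23 measured genes of the YAP and mechanical response list, 8 were at least 2-fold lower and 0 higher, with a median of -0.45 at percentile 0. The matricellular genes CCN2 (6.55 against 9.04) and CCN1 (3.97-fold) were lower, as were NT5E (4.25-fold) and CRIM1 (8.09 against 9.68). The 25 measured junction genes had a median of 0.09, inside the random range, but the tight junction genes CLDN4, CLDN7 and CLDN1 were 3.56-fold, 3.02-fold and 2.79-fold lower, and OCLN 1.57-fold lower.

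Positional genes were measured in part. Of the HOX genes, which record position along the body, 9 were measured. The median of 0.24 lay inside the random range, and 8 of the 9 differences were positive. HOXC9 and HOXC6 were 1.90-fold and 1.69-fold higher in volar, HOXC4 at least 1.32-fold higher, and HOXC13 1.37-fold lower. Among 16 measured limb and positional transcription factors, 4 were at least 2-fold higher and 2 lower. Their median of 0.23 lay just inside the random range at percentile 97.03, and outside it as higher in 4 alternatives, with medians from 0.20 to 0.46. EN1, a homeobox gene of the ventral limb ectoderm, read 5.83 in volar and 3.45 in nonvolar cells by its single probe set, so that the bound was only 1.15-fold. DLX5 was 2.64-fold (0.85 on the log2 scale by the median of its probe sets) and TBX3 2.44-fold higher (0.91 likewise), and IRX1 2.54-fold lower.

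Signalling lists were mixed. In the WNT list the median was 0.00, inside the random range, with 2 of 23 measured genes at least 2-fold higher and 2 lower. WNT10A was at least 3.94-fold higher, and WNT4 was 7.06-fold higher by its brightest probe set (8.68 against 5.86) but by 0.59 on the log2 scale by the other. FZD7 was at least 1.84-fold and DKK3 2.69-fold lower. The BMP and TGF-beta list had a median of -0.37 at percentile 0.01, which ran from -0.78 to -0.17 over the alternatives, with 3 of 21 measured genes at least 2-fold higher and 4 lower. LTBP1, which binds latent TGF-beta, was at least 4.55-fold lower and INHBA 2.39-fold lower, whereas TGFBI was 2.80-fold and BAMBI 2.16-fold higher, or 0.77 on the log2 scale with a pseudocount of 32. In the EGF and FGF list, with a median of -0.62 at percentile 0, 6 of 22 measured genes were at least 2-fold lower and 1 higher, and 18 differences were negative. ETV5, PHLDA1 and DUSP4, targets of the MAP kinase pathway, were 4.33-fold, 3.39-fold and 2.70-fold lower, and the receptor FGFR3 was 2.74-fold higher. The Notch list, with 16 measured genes, had a median of -0.14 inside the random range. HES4 (2.18-fold, or -0.90 on the log2 scale with the pseudocount) and HES1 (1.86-fold) were lower, and LFNG and HES5 1.82-fold and 1.45-fold higher. The list stood apart as lower in 2 alternatives (-0.36 and -0.24). The retinoid list had 5 of 15 measured genes at least 2-fold lower and 0 higher, and its median of -0.15 lay inside the range, but at -1.30, -0.82 and -0.43 it lay outside as lower in 3 alternatives. ALDH1A3, an enzyme that makes retinoic acid, was 5.43-fold lower, SDR16C5 3.55-fold (-0.82 on the log2 scale by the median of its probe sets), CRABP2 2.86-fold and DHRS9 at least 1.25-fold lower.

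Metabolic and stress genes differed gene by gene. The NRF2 and xenobiotic list was the other list placed as higher, with a median of 0.38 at percentile 100 (0.58 with the stricter filter), 5 of 20 measured genes at least 2-fold higher and 2 lower. The higher members included the aldo-keto reductases AKR1B10 (12.8-fold, 11.64 against 7.97), AKR1C2 (3.79-fold) and AKR1C1 (3.38-fold), and the AKR1C genes are close paralogs. HMOX1, which degrades heme, was 4.78-fold lower. The hypoxia and glycolysis list (median -0.04, 19 measured) and the list of immediate early and stress genes (median 0.02, 26 measured) lay inside the random range. In these, ANGPTL4 was 3.84-fold and PFKFB3 2.31-fold lower, ALDOC was 2.65-fold higher, EGR3 was 4.39-fold lower and EGR1 2.39-fold higher. With the median of each gene's probe sets, the log2 differences were only -0.52 for PFKFB3, -0.15 for EGR3 and 0.49 for EGR1. The 21 measured transport genes had a median of -0.10, inside the random range, and were placed as lower (-0.18, percentile 1.49) in 1 alternative. The water and glycerol channel AQP3 was 4.38-fold higher (12.86 against 10.73), the proton pump ATP12A 5.70-fold lower and the glucose carrier SLC5A1 at least 2.94-fold lower.

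Markers of other cell types and of skin appendages were lower in part. Of 6 measured sweat gland markers, 3 were at least 2-fold lower, with a median of -1.18 at percentile 0, or -0.14 with no level filter. These were keratins of simple epithelia, KRT7 (at least 24.3-fold), KRT19 (8.64-fold) and KRT18 (2.66-fold), and KRT8 was 1.94-fold lower. Of 12 measured hair follicle and sebaceous markers, 6 were at least 2-fold lower and 1 higher, 8 of the 12 differences were negative, and the median was -0.59 at percentile 0.01. In 3 alternatives this list fell inside the random range, with medians from -0.11 to -0.04, while over all alternatives its median ran from -1.20 to -0.04. The transcription factor SOX9 was at least 16.1-fold lower (5.59 against 9.63), KRT75 9.02-fold, GATA3 4.64-fold and NFATC1 at least 2.31-fold lower (-0.30 on the log2 scale by the median of its probe sets). KRTAP2-3, a keratin-associated protein of hair, was at least 22.2-fold lower, from a probe set that may read its paralogs. Of 8 measured fibroblast markers, 3 were at least 2-fold lower and 3 higher, 4 differences were negative and 4 positive, with a median of -0.46 at percentile 0.77. That median turned to 0.02 with no level filter and was -3.27 with the stricter filter, which left 4 measured members. POSTN was at least 19.4-fold lower (5.41 against 9.89), FAP at least 5.70-fold and COL6A1 5.19-fold, although COL6A1 differed by only -0.86 to -0.15 by its other probe sets. DCN was at least 2.54-fold higher by its brightest probe set, but by only 0.25 on the log2 scale with the probe sets that lack the suffixes for shared targets. The collagen genes COL1A1, COL1A2 and COL3A1, named here after their values were seen, were below the filter on both arrays. Among 7 measured melanocyte markers, with a median of 0.10 inside the random range, MITF was 2.73-fold lower and TYRP1 at least 2.34-fold higher, or 0.90 on the log2 scale with the pseudocount. The endothelial list had 2 measured genes (TIE1 and EGFL7), the immune list 3 (TYROBP, CD74 and CD68) and the Merkel cell list 1 (SYP), none of them at 2-fold. Among the largest differences that belong to no list, SERPINF1, a secreted serpin, was at least 7.51-fold higher by its brightest probe set, with the same sign in its other 4, and DAPL1 was 12.8-fold higher (9.53 against 5.85).

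Several checks were made within the arrays. The 15 measured reference genes had a median difference of 0.05, inside the random range, with none at 2-fold, and the farthest were POLR2A (1.62-fold lower) and GUSB (1.62-fold higher). The 26 spike-in probe sets above the filter differed by at most 0.16. Of 400 genes at least 2-fold different with other measured probe sets, 394 (98.5%) had the same sign in all of them, against 1918 of 3391 genes (56.6%) under 1.2-fold. The log2 difference of a gene's other measured probe sets lay a median of 0.14 from that of its brightest probe set, and 0.55 at the 95th percentile. Of 30 lists given a percentile, 2 stood apart as higher and 15 as lower, where 1.5 would be expected outside the central 95% for lists of randomly drawn genes. Members of a list are not independent, so 1.5 does not say how many lists would stand apart between any 2 cultures. These checks cover measurement error within the arrays, not the quality of the RNA, and the spread between cultures or donors was not measured.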

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

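The alternative with values below the filter raised to it was chosen after the data were seen, and the others before. The counts of genes at least 2-fold higher and lower, 314 and 449, were 156 and 259 with the level filter at the 75th percentile, which tests fewer genes (6179), 196 and 324 with a pseudocount of 32, which shrinks differences of dim genes, and 861 and 930 at a 1.5-fold threshold. In the other alternatives they ran from 245 to 360 higher and from 352 to 512 lower. The share of higher genes among those past 2-fold, 41.2%, ran from 37.6% to 41.8%, and was 48.1% at 1.5-fold. No scaling moved the median difference of measured genes by over 0.1. The number of lists placed as higher went from 2 to 4 with the stricter filter and to 4 with the pseudocount, where the early differentiation and limb lists joined, and the cause was not tested. The fibroblast median turned from -0.46 to 0.023 with no filter, which takes in all 19 analysed members, and was -3.27 with the stricter filter, which left 4. CDKN2A turned from -1.17 to 0.35 with the median of probe sets, because its probe sets disagree. Over all alternatives, 228 list medians were counted as moving by less than the spread of random lists and 72 by more. The 228 include every median of the lists given no percentile, for which no such spread exists. Only 1, the fibroblast median, turned its sign from a list that stood apart. Of the lists that did not stand apart, 3 also turned sign near 0. The stress list went from 0.02 to as low as -0.08, the transport list from -0.10 to 0.00159 and the reference genes from 0.05 to -0.01. The WNT median, at 0.00, ran from -0.17 to 0.11. With no filter, which adds dim members, the medians of the cytokine (-0.50), migration and matrix (-0.35), BMP and TGF-beta (-0.17) and sweat gland lists (-0.14) were nearer 0. Of 109 named genes at 2-fold, 27 fell under 2-fold in at least 1 alternative, among them DCN (0.25 with the specific probe sets), WNT4 (0.59 with the median of probe sets), EN1 (0.21 with low values raised) and MKI67 (0.99 with the median of probe sets). KRT9 stayed between 5.67 and 6.17, FLG between -4.81 and -4.14 and CDK1 between 2.71 and 3.42. No paired analysis was possible because each site has 1 array, and no replicate could be left out. Signal close to background limits fold differences of dim genes, and signal near the top of the scale limits those of KRT5 and KRT14.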

Other observations

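The tests on scaling, RNA quality, differentiation stage, growth state, fibroblasts and appendage cells were chosen after the patterns were seen, and those on replication genes and serine enzymes before their values were seen. The gene families and genes in the next paragraph, and PHGDH further on, were picked after their values were seen.

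The keratin family split by site. Of 24 measured keratin genes, 5 were at least 2-fold higher in volar (KRT1, KRT2, KRT3, KRT9 and KRT222) and 9 at least 2-fold lower (KRT7, KRT13, KRT18, KRT19, KRT23, KRT31, KRT75, KRT77 and KRT80). KRT13, a keratin of internal stratified epithelia, read 5.80 in volar and 10.42 in nonvolar cells. Under centring and quantile normalization the split was again 5 and 9, and with loess 5 and 10, while raising low values to the filter left 3 and 9. Among the LCE genes, a cluster of cornified envelope genes, 11 of 15 measured were lower and 0 higher, and among the SPRR genes 7 of 10, with the same counts under centring, quantile and loess scaling. With a pseudocount of 32, or with low values raised to the filter, 9 of 15 LCE and 7 of 10 SPRR genes were lower. With only the specific probe sets, 8 of 10 and 6 of 9 were lower. Of the distal-less homeobox genes, 3 of 4 measured were higher (DLX1, DLX2 and DLX5). With the median of probe sets, 1 of 2 measured was higher, and with only the specific probe sets 2 of 2. DLX1 read 6.79 in volar and 4.28 in nonvolar, below the filter. DLX2 read 8.87 in volar, but its difference ran from 0.06 to 2.87 over the alternatives. Of 6 measured AKR1 genes, 4 were higher and 0 lower under every scaling.

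Cell cycle genes were higher and cornified envelope genes lower in volar, with medians of 1.71 and -2.67. Of the poly-A spike-in probe sets above the filter, the farthest from 0 differed by -0.13. They were normalized with all other values, so a labelling difference shared by all transcripts cannot be judged from them. The other spike-ins, which differed by at most 0.16, are hybridisation controls and do not test labelling. A scaling difference cannot be judged either, for the same reason. Fewer differentiated cells of every stage are argued against by the early differentiation genes, whose median was 0.18. Of these 17 genes, however, 10 were higher and 7 lower in volar. Some of them, such as KRT1 (13.60 against 12.34) and KRT10 (13.41 against 12.76), read high on the scale, where a shift may be compressed. RNA degradation stays open, since actin and GAPDH, whose 3' minus 5' values differed between arrays by 0.0306 at most, read near the top of the scale, where a shift is compressed, and the ribosomal RNA controls (-0.27 and 0.29) have no poly(A) tail. It also stays open whether the cultures differed in density at harvest or in passage, on which the volar labels are not uniform, and with 1 array per site neither can be told apart from the site. A lasting difference between volar and nonvolar cells is the biological hypothesis and was not tested beyond these arrays.

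FN1, VIM, POSTN, KRT7 and KRT19, genes of stroma or simple epithelia picked from 3 lists after their values were seen, were higher in nonvolar. The fibroblast list itself split into 4 negative and 4 positive differences. Among the positive, DCN was at least 2.54-fold higher in volar, but by only 0.25 on the log2 scale with the specific probe sets. The median of that list, -0.46, turned to 0.02 with no level filter and was -3.27 with the stricter filter, which left 4 measured members. Fibroblasts would bring their abundant interstitial collagens, but the 16 probe sets of COL1A1, COL1A2 and COL3A1, all below the level filter on both arrays, had a median difference of 0.00855 and a lowest difference of -0.43, which argues against fibroblasts there as the whole cause. The sweat gland list was lower in volar, with a median of -1.18, or -0.14 with no level filter. Its members past 2-fold were keratins of simple epithelia (KRT7, KRT19 and KRT18), so it cannot show whether gland cells were present. Keratinocytes from hair follicles may contribute, with a median of -0.59 for the follicle list and SOX9 and KRT75 among its lower members in volar. That list fell inside the random range in 3 alternatives, with medians of -0.04, -0.11 and -0.11, while its lowest median over the alternatives was -1.20. Of its 28 analysed members, 12 were measured in these cultures, and none of the list is in another list. Hairless and hairy skin differ in follicles by site, so this and a site difference in interfollicular cells cannot be told apart here.

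If the cell cycle difference reflects a larger share of cycling cells in volar, replication and repair genes outside the fixed list should be higher too. Of 28 such measured genes, 17 were at least 2-fold higher and 0 lower. Among the 17, CDT1, GINS4, POLE2, RAD51AP1, BRCA1 and FANCI fell under 2-fold with low values raised to the filter. In all, 27 of the 28 differences were positive, and the median was 1.16, above all 10000 random lists. These are transcripts, and they share regulators with the fixed list, so the result is consistent with that hypothesis without showing it. PHGDH, the first enzyme of serine synthesis, read 9.37 in volar and 6.81 in nonvolar. The hypothesis that serine and one-carbon synthesis genes were higher as a group asked for a median of at least 0.5 over the other 8 enzymes, and the median was 0.31, at percentile 97.93. PSAT1 (1.70) and SHMT1 (1.75) were past 2-fold, and PSPH, MTHFD2 and GCSH were slightly lower in volar. The prediction of at least 0.5 was therefore not met. The group still lay outside the central 95% of random lists as higher, and its members ran from -0.28 to 1.75. A group difference smaller than 0.5 is not excluded by these values.

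Probe sets outside the gene table also differed. Of 1125 measured probe sets with no gene named here, 26 were at least 2-fold higher and 36 lower, and of 903 that name several genes, 17 and 43.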
